A study of Mus musculus with 6 samples.

How the data were processed

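The series measured gene expression in splenocytes, the cells isolated from spleen, of female NZB/WF1 mice, a hybrid strain that develops a lupus-like disease. Mice received an implant with 17-beta estradiol (E2), an implant with 17-alpha-ethinyl estradiol (EE) or an empty placebo implant at 6 to 7 weeks of age, and spleens were taken after 9 weeks. Total RNA was counted with a NanoString mouse immunology panel on the nCounter system, in which colour-coded probes are hybridised to RNA and counted without amplification or sequencing. Each of the 3 groups held 2 samples, named here by the numbers in their labels. The labels do not tie each sample to a mouse, so p-values measure the spread between these samples. Implant doses and the assignment of samples to cartridges or lanes were not given in the sources used here.

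The deposited values were barcode counts per probe, whole numbers that differed in total between samples, and they were treated as raw counts. The geometric mean of the 12 reference genes that could be named was nearly level, from 1117.0 to 1184.8 per sample. Scaling on reference genes before deposit is therefore likely, and the values may not be raw. Background and normalisation steps before deposit were not given in the sources used here. Negative-control counts were not subtracted to 0, and positive-control counts were unequal between samples. The table held 575 rows, of which 561 were genes and 14 were spiked-in controls, of which 6 with a mean of at least 20 counts were taken as positive and 8 as negative. The controls held 2.82% to 4.71% of each sample's counts and stayed out of totals and tests. Gene symbols came from a RefSeq gene table of assembly GRCm38.p6 through transcript identifiers without their versions, which named 549 gene rows and left 12 unnamed. Of the 14 reference genes that the labels count, 12 were named and used here. The number of value columns without a sample was 0.

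Gene totals ranged from 646299 to 863942 counts per sample. Genes with a mean of at least 20 counts over the 6 samples were tested, which kept 457 and left out 104. The background, taken as the mean plus 2 SD of the negative controls, lay between 10.2 and 13.7 counts, and 475 to 498 genes per sample exceeded it. Counts near this level have little precision, so a fold against such a level is uncertain. The Klra genes are near-identical members of 1 receptor family whose probes could count each other's transcripts, so values of single members are uncertain.

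Tests used the edgeR quasi-likelihood method (edgeR 4.0.16 in R 4.3.3) with trimmed-mean (TMM) scaling and a model of group means over all 6 samples, which share 1 estimate of the spread with 3 residual degrees of freedom. The common biological coefficient of variation was 0.0892. This test was planned for raw counts, and limma on log2 of the deposited values for normalised ones. That limma fit was not run, and the limma fits among the alternatives carry TMM scaling or quantile normalisation. The p-values are two-sided and adjusted by the Benjamini-Hochberg method over the 457 genes of a comparison, with a threshold of 0.05 and no minimum fold. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. Levels are given as TMM-scaled CPM, counts relative to the scaled sample total.

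A total of 30 gene lists were fixed from textbook knowledge before the data were examined, as were the designs, the rule for named genes and most alternatives. The 29 lists with at least 4 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, which compares a list with all other genes. Camera with an estimated correlation, and fry, which tests whether members move on balance in one direction, were run beside it. The rule for named genes took, per comparison, up to 12 largest increases and 12 largest decreases past the threshold whose samples did not overlap, filled up to 6 by lowest p where needed. It added the 2 to 4 members with the lowest p of each list discussed, the reference genes as a group, and Ifng, Il6, Il10, Il17a, Tnfsf13b, Irf7, Foxp3 and Prdm1 whatever their result. A further gene that the rule names is not reported here.

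The alternatives comprised DESeq2 1.42.0, limma on log2 values with a pseudocount of 1 or 10 and with a trend, a robust prior for the spread, quantile normalisation, other filters (none, or a mean of 50), an adjusted p of 0.1, only the groups compared, and each sample left out in turn. Other scalings used the reference genes or the median gene. Chosen after seeing the data were scaling on column totals, scaling on positive controls, TMM without S100a8, S100a9 and Camp, subtraction of the negative-control mean, and a different placebo sample for each estrogen in the correlation of their fold changes. For the shared placebo samples, 100 simulated data sets without effects were drawn.

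The scripts were tested on simulated data with counts drawn for the 457 genes at the real means, totals and dispersions. Of these genes 200 were changed, in equal numbers up and down. Real changes over 2-fold against placebo were uneven, with 58 up and 7 down for E2 and 79 and 10 for EE. The shares below hold for balanced changes and may not carry over. For E2 against placebo, 74.6% of genes changed 1.5-fold were recovered, 95.5% of those changed 2-fold and 100% of those changed 4-fold, and 3.50% of unchanged genes were called. For EE against placebo the shares were 71.6%, 94.0%, 100% and 1.95%. For EE against E2 they were 73.1%, 98.5%, 100% and 1.17%. Figures were drawn with matplotlib 3.10.9.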

Results

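Expression of immune genes was counted in splenocytes of lupus-prone female mice that carried an E2, EE or empty implant, with 2 samples per group. E2 is the natural estrogen, and EE is estradiol with an ethynyl group at the 17-alpha carbon. Gene totals were 810223 and 771344 counts in E2 replicates 1 and 2, 646299 and 673384 in EE replicates 11 and 14. They were 822812 and 863942 in placebo replicates 22 and 26. Taken as raw counts, samples of a group differed by more than counting noise in each group. Chi-square over its degrees of freedom was 14.7 for E2, 3.71 for EE and 19.3 for placebo. Scaling before deposit would change the counting noise, so these ratios are approximate. The first principal component held 84.5% of the variance and parted both estrogen groups from placebo, and the second held 9.78% and parted E2 from EE. The transcripts of S100a8, S100a9 and Camp together took 22.4% and 26.8% of the counts in the E2 samples, 12.5% and 13.8% in the EE samples, and 1.11% and 0.651% in the placebo samples.

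Scaling moved the fold changes against placebo. With TMM, log2 fold changes lay 0.63 higher for E2 and 0.75 higher for EE than with scaling on the 12 named reference genes, and 0.13 higher for EE against E2. Directions below are therefore given relative to the panel as a whole. Since the deposited values were likely scaled on reference genes already, TMM scaling would undo that step. The numbers of changed genes below rest on treating the values as raw counts.

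The comparison of E2 with placebo asked which immune transcripts differ in the spleen under the natural estrogen. All 9 tested neutrophil markers rose, with a median log2 fold change of 2.53. Among them were Camp, which encodes the antimicrobial peptide cathelicidin (5.50 ± 0.22 SE), S100a8 and S100a9, the subunits of calprotectin (5.32 ± 0.26 and 5.19 ± 0.26), and Ltf, lactoferrin (4.25 ± 0.27). All 6 tested genes of the erythroid, megakaryocyte and platelet list rose as well (median 1.997), including the transferrin receptor Tfrc (3.14 ± 0.14) and the blood cell transcription factor Tal1 (3.34 ± 0.18). Placebo counts of its members Cd59b (11 and 6) and Gp1bb (17 and 12) were near the background, so the size of their folds is uncertain. On reference genes 5 of these 6 genes and 7 of the 9 neutrophil markers were higher. T cell markers fell in 14 of 17 cases (median -0.56), and genes of natural killer (NK) and cytotoxic cells fell in 10 of 17 (median -0.71). S100a8 averaged 165144 ± 31928 TMM-scaled CPM in E2 and 4137 ± 1495 in placebo (SD, n = 2 each).

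Of 457 genes, 134 were higher and 104 lower in E2 than in placebo, and 58 rose and 7 fell more than 2-fold. With scaling on the reference genes the split was 54 higher and 286 lower, and with scaling on the median gene 104 and 186. Scalings chosen after seeing the data gave 69 and 255 on column totals and 51 and 285 on positive controls. A total of 49 genes were higher and 80 lower under each of the 8 scalings run. Both E2 samples lay beyond both placebo samples for 357 genes, or 78.1%, where chance gives 33.3%. Without E2 replicate 2, 155 genes changed, 98 of them higher and 57 lower.

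Beyond the neutrophil list, the largest increases were those of Ctsg, which encodes the neutrophil protease cathepsin G (5.89 ± 0.41), the myeloid lectin receptor Clec5a (4.13 ± 0.21) and the monocyte-attracting chemokine Ccl12 (3.95 ± 0.36). Placebo counts of Ctsg were 29 and 10 and those of Ccl12 were 9 and 5, near the background, so the size of both folds is uncertain. The erythroid adhesion gene Icam4 (3.50 ± 0.24) followed, and after Tal1 and Tfrc came the leukotriene B4 receptor gene Ltb4r1 (2.89 ± 0.25) and Abcb10, a mitochondrial transporter gene used in haem synthesis (2.82 ± 0.15). The largest decreases were those of Gzma, the cytotoxic protease granzyme A (-1.72 ± 0.21), the NK receptor gene Klra4 (-1.60 ± 0.25) and the interleukin-7 receptor gene Il7r (-1.37 ± 0.11). Next came the transcription factors Eomes (-1.13 ± 0.19) and Tbx21 (-1.09 ± 0.26), Cd160 (-1.04 ± 0.34), Klra7 (-1.03 ± 0.25), Cd3e of the T cell receptor complex (-0.97 ± 0.12) and the glucocorticoid receptor partner Fkbp5 (-0.96 ± 0.19). The T cell factor Tcf7 and the interleukin-21 receptor gene Il21r both fell by 0.93, and the chemokine receptor gene Ccr9 fell by 0.92. The calls of Tbx21 (adjusted p = 0.0537) and Cd160 (0.162) were lost without E2 replicate 1, that of Klra7 (0.0633) without E2 replicate 2, and that of Cd160 without placebo replicate 26 (0.124) and with DESeq2 (0.0638). Over the alternatives the lowest adjusted p was 1.43e-08 for Tbx21, 6.05e-07 for Cd160 and 2.65e-07 for Klra7, and the highest were those just given.

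Camera called 4 lists higher in E2 than in placebo. These were neutrophil markers (adjusted p = 2.85e-09, 9 of 9 higher over all genes and 9 adjusted over the list alone), erythroid, megakaryocyte and platelet genes (3.40e-05, 6 and 6), monocyte and macrophage markers (0.0013, 15 of 19 and 15) and reference genes (0.0229, 11 of 12 and 11). The monocyte and macrophage list had a median of 0.71, with Itgam at 2.26 and Trem1 at 2.14, but its median was 0.07 when scaled on reference genes, with 5 members higher and 2 lower. In EE against E2 this list split, with 5 members higher and 4 lower. Itgam (-0.67) and Trem1 (-1.245) were lower there, as neutrophil markers were, while C1qa (0.93) and C1qb (0.91) were higher. Its call in E2 may therefore not be separate from that of the neutrophil markers. The reference genes had a median of 0.59, led by G6pdx (1.60) and Oaz1 (0.83), and this turned to -0.04 when they were the scale, with 2 higher and 4 lower, and to -0.10 on positive controls. Oaz1 then lost its call on both (adjusted p = 0.185 and 0.429, range over the alternatives 2.88e-12 to 0.429). The 3 lists called lower were T cell markers (2.68e-05, 14 of 17 lower and 15 adjusted over the list alone), NK and cytotoxic cell genes (0.00314, 10 lower, 1 higher, and 11 and 1) and follicular helper T and germinal centre genes (0.0159, 7 of 13 and 7), with Btla at -0.88 and Bcl6 at -0.68. With an estimated correlation the adjusted p was 0.67 for the neutrophil, erythroid and follicular helper lists and 0.679 for the other 4, so 0 of the 7 calls held by camera, with 0 of 29 lists at an unadjusted p under 0.05, while fry called 17. Medians over the 8 scalings ranged from 1.84 to 2.53 for neutrophil markers, from 1.32 to 2.01 for the erythroid list, from -1.24 to -0.56 for T cell markers and from -1.38 to -0.71 for NK and cytotoxic genes. The call of the follicular helper list was lost when scaled on reference genes (adjusted p = 0.0665) and on positive controls (0.0598), with adjusted p from 0.00306 to 0.0665 over the alternatives. The reference gene call was lost without E2 replicate 2 (0.0999) and without EE replicate 11 (0.0586), with adjusted p from 0.00306 to 0.275 over the alternatives.

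B cell markers had a median of -0.26 in E2 against placebo, with 7 of 16 lower and 1 higher over all genes, 8 and 1 adjusted over the list alone, and a camera adjusted p of 0.171. When scaled on reference genes 15 of 16 were lower and 1 higher, with a median of -0.89, and the median was -0.95 on positive controls. Cd22 fell by 0.70 and Pax5 by 0.54, while Cd24a, which erythroid and granulocytic cells also carry, rose by 2.30. Complement genes had 9 of 13 higher and 2 lower, the same counts adjusted over the list alone, and a camera adjusted p of 0.217, with C3 at 2.30 and Cfp at 0.72. When scaled on reference genes 3 were higher and 4 lower, and the median went from 0.71 to 0.07 (0.015 on positive controls). Of the 14 interferon-stimulated genes tested, 2 rose and 1 fell (1 and 0 adjusted over the list alone), with Ifih1 at 0.79 and Cxcl9 at -0.48 (camera adjusted p = 0.731). In contrast, 0 were higher and 10 lower when scaled on reference genes, where the median went from -0.11 to -0.74. The call of Cxcl9 was lost without E2 replicate 1 (adjusted p = 0.161), EE replicate 14 (0.0552) or placebo replicate 26 (0.0908) and with DESeq2 (0.0989), with a range of 3.55e-07 to 0.161 over the alternatives. When scaled on reference genes the calls of Cfp (adjusted p = 0.54, range over the alternatives 1.88e-07 to 0.838) and Ifih1 (0.412, range 1.05e-04 to 0.647) were lost.

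**Figure D1:**
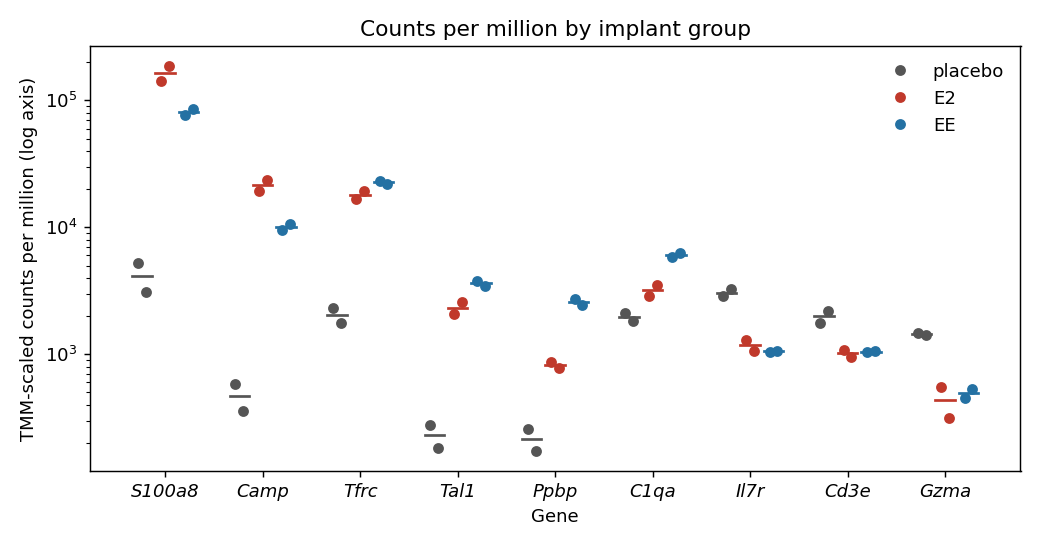
TMM-scaled CPM (vertical log axis) of 9 genes in the 6 samples. Points are samples and bars are group means. S100a8, Camp, Tfrc, Tal1, Ppbp and C1qa lie above placebo in both estrogen groups and Il7r, Cd3e and Gzma below it; the directions held under 8 scalings, but C1qa in E2 was only 0.015 above placebo in log2 units on positive controls.

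The comparison of EE with placebo put the same question for the synthetic estrogen. All 6 tested erythroid, megakaryocyte and platelet genes rose, with a median of 3.42, among them Tal1 (3.98 ± 0.18), the platelet chemokine gene Ppbp (3.58 ± 0.17), Tfrc (3.48 ± 0.14) and the platelet integrin gene Itga2b (3.35 ± 0.31). All 6 were also higher on reference genes, but the folds of Cd59b and Gp1bb again rest on placebo counts near the background. Neutrophil markers rose in 7 of 9 cases (median 1.38), including Camp (4.43 ± 0.21), S100a8 (4.29 ± 0.25), S100a9 (4.10 ± 0.24) and Ltf (3.29 ± 0.28). All 17 tested T cell markers fell (median -0.78), with Il7r at -1.53 ± 0.11, Tcf7 at -1.16 ± 0.11, Cd247 at -0.96 and Cd2 at -0.80. Il7r averaged 1057 ± 10.8 CPM in EE and 3060 ± 273 in placebo (SD, n = 2 each).

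Of 457 genes, 136 were higher and 123 lower in EE than in placebo, and 79 rose and 10 fell more than 2-fold. The split was 66 higher and 301 lower when scaled on reference genes, 111 and 191 on the median gene, 102 and 217 on column totals and 41 and 327 on positive controls, of which the scalings on totals and positive controls were chosen after seeing the data. Under each of the 8 scalings 41 genes were higher and 99 lower. Samples of the groups did not overlap for 370 genes, or 81.0%, where chance gives 33.3%. Genes called lower numbered 74 without EE replicate 14.

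Ctsg (5.53 ± 0.41), Icam4 (4.14 ± 0.24), Abcb10 (3.46 ± 0.15) and Clec5a (3.23 ± 0.22) were also among the largest increases. Besides Il7r and Tcf7, the largest decreases were those of Ccr9 (-1.74 ± 0.15), Gzma (-1.55 ± 0.21), the interleukin-25 receptor gene Il17rb (-1.51 ± 0.38), Klra4 (-1.32 ± 0.24), the perforin gene Prf1 (-1.21 ± 0.23) and Eomes (-1.19 ± 0.20). Counts of Il17rb were 16 and 12 in EE, near the background, and 45 and 84 in placebo, so the size of its fold is uncertain. The chemokine receptor gene Cxcr6 (-1.07), the NK receptor gene Klrd1 (-1.04), the T cell factor Lef1 (-0.99) and Runx3, a transcription factor of cytotoxic lymphocytes (-0.98), also fell.

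Camera called 5 lists higher in EE than in placebo. The erythroid, megakaryocyte and platelet list had an adjusted p of 2.26e-07 (6 of 6 higher, 6 adjusted over the list alone), neutrophil markers 5.48e-04 (7 of 9 and 7), monocyte and macrophage markers 5.48e-04 (14 of 19 higher and 1 lower, 15 and 1 adjusted over the list alone), complement genes 0.0198 (9 of 13 higher and 2 lower, and 9 and 2) and reference genes 0.0138 (10 of 12 and 11). Monocyte and macrophage markers had a median of 1.27 and included Clec5a, the complement genes C1qa (1.63) and C1qb (1.71) and the growth factor receptor gene Csf1r (1.16). Complement genes had a median of 1.32, with Cfp, which encodes properdin, at 1.40. Over the 8 scalings medians ranged from 2.41 to 3.42 for the erythroid list, from 0.38 to 1.38 for neutrophil markers, from 0.27 to 1.27 for monocyte and macrophage markers and from 0.32 to 1.32 for complement genes. When scaled on reference genes, 5 neutrophil markers were higher and 1 lower, 13 monocyte and macrophage markers were higher and 4 lower, and 8 complement genes were higher and 4 lower. The reference genes had a median of 0.64, with Oaz1 at 1.32 and Tubb5 at 0.997, and turned to -0.11 when they were the scale, with 3 higher and 3 lower, and to -0.36 on positive controls, where Tubb5 turned to -0.01. On positive controls Csf1r (adjusted p = 0.352, range over the alternatives 3.27e-17 to 0.352) and Oaz1 (0.0802, range 3.40e-30 to 0.0802) lost their calls. Tubb5 lost its call on reference genes as well (0.0883, range 3.79e-14 to 0.938). The lists called lower were T cell markers (1.04e-06, 17 of 17 and 17) and NK and cytotoxic cell genes (0.0171, 10 of 17 and 10), with Klrd1 at -1.04 and Klra8 at -0.95, and their medians ranged from -1.78 to -0.78 and from -1.45 to -0.44. With an estimated correlation the adjusted p was 0.655 for the erythroid, neutrophil, complement, T cell and NK lists and 0.688 for the other 2, so 0 of the 7 calls held by camera, with 1 of 29 lists at an unadjusted p under 0.05, while fry called 22. The NK call was lost when scaled on reference genes (adjusted p = 0.0907, range over the alternatives 0.00573 to 0.0976), the complement call without a filter on low counts (0.0813, range 0.0135 to 0.0813) and with limma (0.0561), and the reference gene call without EE replicate 11 (0.0601, range 0.00201 to 0.189).

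B cell markers had a median of -0.28 in EE against placebo, with 9 of 16 lower and 1 higher, the same counts adjusted over the list alone, and a camera adjusted p of 0.109. When scaled on reference genes 15 of 16 were lower and 1 higher, with a median of -1.04, and the median was -1.29 on positive controls. Pax5 fell by 0.70 and Cd22 by 0.78, and Cd24a rose by 2.93. Of 14 interferon-stimulated genes 4 rose and 2 fell, as when adjusted over the list alone (camera adjusted p = 0.868), with Ifih1 at 1.04 and Irf7 at 1.08. In contrast, 0 were higher and 11 lower when scaled on reference genes, where the median went from -0.12 to -0.87. Neither kept its call when scaled on reference genes: the adjusted p was 0.119 for Ifih1 (range over the alternatives 1.05e-07 to 0.871) and 0.108 for Irf7 (6.48e-06 to 0.752).

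**Figure D2:**
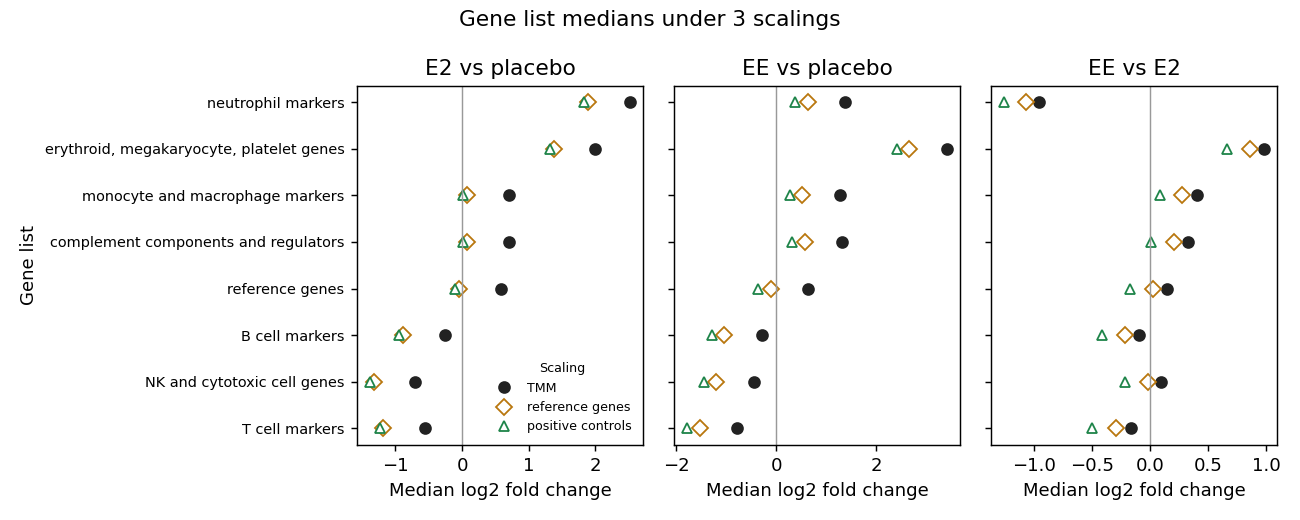
Median log2 fold change (horizontal axes) of 8 gene lists in the 3 comparisons, with TMM scaling, scaling on reference genes and scaling on positive controls. Neutrophil and erythroid, megakaryocyte and platelet medians stay above 0 and T cell medians below 0 against placebo, while the reference gene median turns from 0.59 to -0.04 for E2 and from 0.64 to -0.11 for EE.

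The fold changes of both estrogens against placebo correlated across the 457 genes, which are not independent replicates, with Pearson r = 0.919 and Spearman rho = 0.905. Both comparisons share the placebo samples, and simulated data without effects gave r = 0.45. The covariance was 0.867 against 0.0158 in the simulations, and 87.7% of genes had the same sign against 65.4%. A total of 116 genes were higher in both comparisons, where independent lists would share 39.9, and 88 were lower in both, where they would share 28.0. Through the shared placebo samples these lists are not independent, and their overlap was not simulated, so both baselines may be too low. With a different placebo sample set against each estrogen, a division chosen after the result was seen, r was 0.884 and, the other way round, 0.869, where simulated data without effects gave -0.00145. The number of genes called in opposite directions was 0 by edgeR, DESeq2 and limma, and 1 by edgeR at an unadjusted p under 0.05.

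The direct comparison of EE with E2 asked where estrogens that differ by the ethynyl group differ in response; doses were not given in the sources used here, so matched doses are not established. Genes of the erythroid, megakaryocyte and platelet list were higher in EE, with a median of 0.98 and 4 of 6 members called, including Itga2b (2.03 ± 0.29), Ppbp (1.64 ± 0.15), the platelet glycoprotein gene Gp1bb (1.32 ± 0.28) and Tal1 (0.64). Neutrophil markers were lower in EE, with a median of -0.96 and 6 of 9 called, including Cxcr2 (-1.15 ± 0.25), S100a9 (-1.09 ± 0.22), Camp (-1.08 ± 0.18) and S100a8 (-1.03 ± 0.22). The complement genes C1qa (0.93 ± 0.11), C1qb (0.91 ± 0.15), C6 (0.89 ± 0.15) and Cfp (0.68) were higher in EE. Ppbp averaged 2572 ± 199 CPM in EE and 825 ± 71.1 in E2 (SD, n = 2 each).

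Of 457 genes, 34 were higher and 23 lower in EE than in E2. The split was 23 and 50 when scaled on reference genes, 81 and 18 on column totals and 11 and 125 on positive controls, of which the last 2 scalings were chosen after seeing the data. Samples of the groups did not overlap for 286 genes, or 62.6%, where chance gives 33.3%. Under each of the 8 scalings 6 genes were higher (C1qa, Itga2b, Vcam1, Clu, Cxcl12 and Ppbp) and 3 lower (Clec5a, Ccr9 and Ccl12). This comparison was the least stable: 33 genes changed without E2 replicate 1, 21 without E2 replicate 2, 24 without EE replicate 11, 26 without EE replicate 14, 110 without placebo replicate 22 and 111 without placebo replicate 26, and limma with a pseudocount of 1 called 10. Of the 57 calls, 29, 21, 23 and 24 were kept without these E2 and EE samples in the order given. In the limma fit S100a8 (adjusted p = 0.0849, range over the alternatives 5.54e-10 to 0.182) and Camp (0.0751, range 8.64e-15 to 0.0751) missed the threshold. S100a8 also missed it without E2 replicate 2 (0.0787) and without EE replicate 11 (0.051).

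Among the genes named above, Itga2b, Ppbp, C1qa, C1qb, C6, Cfp and Camp kept their calls with each sample left out. Cxcr2 lost its call without E2 replicate 2 (adjusted p = 0.0902) and without EE replicate 14 (0.0543), with a range of 2.80e-09 to 0.0986 over the alternatives. S100a9 lost it without E2 replicate 2 (0.064, range 5.88e-12 to 0.162). Gp1bb lost its call without E2 replicate 1 (0.053), E2 replicate 2 (0.102) or EE replicate 11 (0.107), with a range of 0.00113 to 0.107. Tal1 lost it without E2 replicate 1 (0.15) or EE replicate 11 (0.0842), with a range of 1.05e-05 to 0.194. In the limma fit C1qb (0.0674), C6 (0.0528) and Cfp (0.0503) also missed the threshold, with highest values over the alternatives of 0.102, 0.0575 and 0.0673.

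Other increases in EE over E2 were those of the chemokine gene Cxcl12 (1.62 ± 0.23), clusterin, Clu (1.20 ± 0.14), the cytokine gene Il1a (0.99 ± 0.28), the Fc receptor gene Fcgr1 (0.90 ± 0.18), the adhesion gene Vcam1 (0.82 ± 0.09) and the macrophage marker Adgre1 (0.80 ± 0.15). Other decreases were those of Ccl12 (-1.27 ± 0.28), the myeloid receptor gene Trem1 (-1.24 ± 0.24), the fibronectin gene Fn1 (-1.10 ± 0.25), Ltf (-0.96), Ltb4r1 (-0.94), Clec5a (-0.90), Csf3r (-0.89) and Ccr9 (-0.82). The call of Il1a was lost without each of the E2 and EE samples in turn (adjusted p from 0.132 to 0.238, and from 0.00587 to 0.238 over the alternatives). Without E2 replicate 2 the calls of Ccl12, Trem1, Fn1, Ltf, Ltb4r1, Clec5a and Csf3r were lost (adjusted p from 0.0585 to 0.125), and without E2 replicate 1 those of Fcgr1 (0.0667) and Adgre1 (0.053). Those of Ccl12, Fn1, Ltf, Ltb4r1, Csf3r and Ccr9 were lost without EE replicate 11 (0.0703 to 0.0843), and those of Fcgr1, Ccl12, Fn1, Ltb4r1, Clec5a and Csf3r without EE replicate 14 (0.0506 to 0.1). For these genes the adjusted p went no higher than 0.125 over the alternatives.

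Camera called the erythroid, megakaryocyte and platelet list (adjusted p = 1.59e-06, 4 of 6 higher and 5 adjusted over the list alone) and complement genes (0.00406, 5 of 13 and 5, median 0.32) higher in EE than in E2. It called neutrophil markers (1.29e-06, 6 of 9 and 8) and T cell markers (0.0178, 3 of 17 and 3, median -0.16) lower, the latter with Cd247 at -0.50, Cd3d at -0.39 and Cd2 at -0.34. Over the 8 scalings the medians ranged from 0.66 to 1.12 for the erythroid list, from 0.0063 to 0.47 for complement genes, from -1.26 to -0.81 for neutrophil markers and from -0.50 to -0.026 for T cell markers. With an estimated correlation the adjusted p was 0.703 for the first 2 lists, 0.766 for neutrophil markers and 0.904 for T cell markers, so 0 of the 4 calls held by camera, with 0 of 29 lists at an unadjusted p under 0.05, and fry called 1 list, the stromal and endothelial genes (adjusted p = 0.0132), which is not among these 4. By fry the adjusted p was 0.121 for the erythroid list, 0.122 for complement genes, 0.181 for neutrophil markers and 0.299 for T cell markers. The T cell call was lost without E2 replicate 1 (adjusted p = 0.301) and without EE replicate 11 (0.0965), with a range of 7.14e-04 to 0.301 over the alternatives. The complement call was lost without E2 replicate 1 (0.0607, range 6.10e-04 to 0.0607). Cd247 lost its call without E2 replicate 1 (0.0743) and without either EE sample (0.0842 and 0.0503). Cd3d and Cd2 lost theirs without E2 replicate 1 (0.147 and 0.191), E2 replicate 2 (0.0904 and 0.102), EE replicate 11 (0.286 and 0.355) and EE replicate 14 (0.0506 and 0.0861). The values without EE replicate 11 are the highest over the alternatives for each of these genes.

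For the other 400 genes the direct comparison made no call, and for 356 of them, or 89%, the 95% interval of the difference lay within 1 log2 unit of 0. Genes chosen after their values were seen illustrate the width: the interval was -0.42 to 0.09 for Il7r, -0.33 to 0.66 for Gzma, 0.05 to 0.63 for Tfrc and -0.97 to 0.25 for Ctsg. The intervals leave room for differences of that size.

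**Figure D3:**
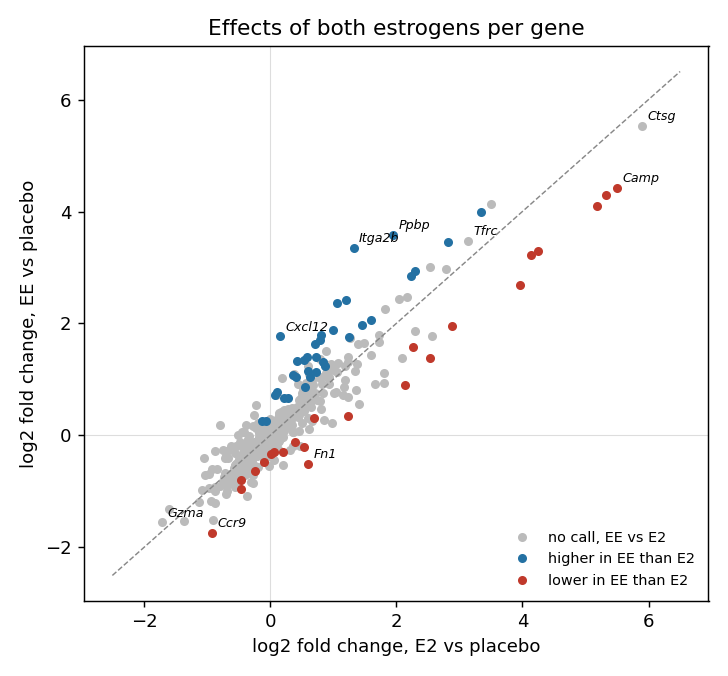
Log2 fold change against placebo for E2 (horizontal axis) and EE (vertical axis), 1 point per gene, coloured by the call of the direct EE against E2 test. Camp lies at 5.50 and 4.43 and Ppbp at 1.95 and 3.58; the dashed line marks equal change.

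Among the genes named whatever their result, Il6 and Il17a had mean counts of 13.8 and 16, below the filter, and were not tested. Tnfsf13b, which encodes the B cell survival factor BAFF, rose in E2 (1.80 ± 0.32, adjusted p = 0.00142) and was at 0.94 in EE (adjusted p = 0.0547, range over the alternatives 0.0153 to 0.889), a difference that did not pass the test (-0.87, adjusted p = 0.11). Counts of Tnfsf13b were 14 and 17 in placebo, near the background, and 47 and 27 in the E2 samples, so the size of its folds is uncertain. The interferon regulator Irf7 rose in EE (1.08, adjusted p = 4.04e-04) and was higher in EE than in E2 (0.71, adjusted p = 0.0215), a call lost without E2 replicate 2 (0.11) and without either EE sample (0.0842 and 0.0895), with a range of 9.81e-04 to 0.143 over the alternatives. It was at 0.37 in E2 (adjusted p = 0.09), and at -0.25 when scaled on reference genes. The regulatory cytokine gene Il10 rose in EE (1.02, adjusted p = 0.0398), but this call was lost without EE replicate 11 (adjusted p = 0.116), EE replicate 14 (0.11) or placebo replicate 26 (0.156) and with DESeq2 (0.112), with a range of 0.00162 to 0.955 over the alternatives. Il10 was at 0.20 in E2 against placebo (adjusted p = 0.699) and at 0.83 in EE against E2 (0.231). Ifng was at 0.11 in E2 and 0.01 in EE, Foxp3 at -0.27 and 0.18, and Prdm1 at 0.20 and 0.33, and none of these passed the test (adjusted p from 0.0811 to 0.965). In EE against E2 they were at -0.10, 0.45 and 0.13, and none passed the test. When scaled on reference genes, Ifng, Prdm1 and, in EE, Foxp3 turned negative against placebo, and Foxp3 (-0.89 in E2, -0.57 in EE) and Prdm1 (-0.42 in both) then passed the test as lower.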

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

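The tests of explanations in this part were all chosen after the results they bear on were seen, while the comparison of EE with E2 was planned. Among genes called in the direct comparison of EE with E2, 7 had effects of opposite sign against placebo with at least 1 of them called, which drew attention to them. The EE over E2 difference was -0.50 for Plaur, -0.74 for Ccr2, -0.34 for Ifitm1, -0.36 for Spn and -0.51 for Csf2rb, and it was 0.38 for Ccr6 and 0.32 for Cd83. These calls were fragile: each was lost without at least 1 of the E2 and EE samples, and the highest adjusted p over the alternatives was 0.0907 for Plaur, 0.109 for Ccr2, 0.197 for Ifitm1, 0.306 for Spn, 0.222 for Csf2rb, 0.792 for Ccr6 and 0.982 for Cd83. On reference genes the calls of Ccr6 (0.237) and Cd83 (0.377) were lost. The opposite signs against placebo depend on the scaling: on reference genes both effects were negative for each of the 7, as a shift shared by all genes gives for small effects. Ccr6 in EE went from 0.25 to -0.50, Cd83 in EE from 0.25 to -0.50, Plaur in E2 from 0.21 to -0.42, Spn in E2 from 0.056 to -0.58, Ifitm1 in E2 from 0.0092 to -0.62, Ccr2 in E2 from 0.53 to -0.10 and Csf2rb in E2 from 0.40 to -0.23. The positive-control totals, which no comparison used for the main values, were 1.25 times as high in EE and 1.09 times as high in E2 as in placebo. Scaling before deposit may have changed these totals.

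With TMM, at least 7 of 9 neutrophil markers and 6 of 6 erythroid, megakaryocyte and platelet genes were higher in each estrogen group. At least 14 of 17 T cell and 10 of 17 NK genes were lower in each, with 1 NK gene higher in E2. On reference genes 7 neutrophil markers were higher in E2, and 5 were higher and 1 lower in EE. Of the erythroid, megakaryocyte and platelet genes 5 were then higher in E2 and 6 in EE, and all 17 T cell markers were lower in each. These list calls were lost with an estimated correlation in camera (adjusted p at least 0.655), and the NK call in EE on reference genes (0.0907). A few abundant transcripts taking the counts would bring the T cell median to about 0 under scalings that do not use totals. The value closest to 0 over 6 scalings was -0.56, which is the main TMM value for E2. The fall of this list was seen under TMM, so that value could not come out near 0 and decides nothing. With S100a8, S100a9 and Camp left out of the TMM scaling the medians were -0.57 for E2 and -0.78 for EE, so these 3 transcripts did not set the TMM values. Even dilution of all lymphocytes by cells without these markers predicts 1 common decrease. T cell markers, and B cell markers without Cd24a, differed among themselves, with Cochran's Q at least 4.74 times its degrees of freedom. Shifts between lymphocyte subsets, or markers that other cells also carry, would give unequal decreases as well. The test treats genes as independent and cannot decide against a change in composition alone. Unequal loss of red cells alone would shift neutrophil and T cell markers alike, but their medians lay at least 2.16 apart. These lists were chosen because they had moved apart. The distance does not bear on the erythroid genes, so red cell loss stays open as a cause of their rise. A change in cell composition, with or without altered expression, may be the cause, as an untested hypothesis.

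The reference genes rose in both estrogen groups after TMM scaling. Their geometric means in the deposited values were level, at most 1.046 times those of placebo. Scaling on reference genes before deposit would fix this in advance, so the level means cannot decide the cause. On positive controls the ratios to placebo were 0.9605 for E2 and 0.8381 for EE. After TMM scaling they were 1.547 and 1.685, so the rise appeared at that step. The reference genes also moved apart, with at least 6 of 12 past the threshold when scaled on their own mean. Differences among them are therefore likely. Which scale is right for these samples stays open.

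In EE 6 of 9 neutrophil markers were lower than in E2, and 4 of 6 erythroid, megakaryocyte and platelet genes and 5 of 13 complement genes were higher; these list calls were lost with an estimated correlation (adjusted p at least 0.703), and the complement call without E2 replicate 1 (0.0607). A single factor per sample, such as assay efficiency, would shift these lists alike, but the erythroid and neutrophil medians lay 1.94 apart. The exact rank-sum p was 4.00e-04, two-sided, over genes, which are not independent. Both lists were chosen because they had moved in opposite directions, so this p adds no evidence to their calls. No single one of the 4 E2 and EE samples decided this distance, which was at least 1.82 without each in turn. Different implant doses or exposure may account for it, and so could the ethynyl group; neither was tested.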

How the results depend on the processing

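Scalings on column totals and positive controls, TMM without 3 genes, background subtraction and the division of the placebo samples were chosen after seeing the data; for the changes below the cause was not tested. Of 157 log2 fold changes of named genes, the direction and the side of the threshold were kept for 148 with DESeq2, 156 with a robust prior, 155 with a trend, 131 when scaled on reference genes, 119 on positive controls, 121 with limma at a pseudocount of 1 and 118 with quantile normalisation, the fewest of the settings run. Genes near the background of 10.2 to 13.7 counts have the least precise values. Scaled on reference genes, 54 genes were higher and 286 lower for E2, 66 and 301 for EE, and 50 lower for EE against E2. On the median gene 186 were lower for E2 and 191 for EE. On column totals 69 were higher and 255 lower for E2, 217 lower for EE, and 99 changed for EE against E2, 81 of them higher. On positive controls the values were 51 and 285 for E2, 41 and 327 for EE, and 136 changed for EE against E2, 11 higher and 125 lower. For EE against E2, quantile normalisation with limma called 15 genes (11 higher, 4 lower), limma with a pseudocount of 1 called 10 (9 and 1), limma with a pseudocount of 10 called 33 (22 and 11), the fit of only these groups called 110 (66 and 44), and an adjusted p of 0.1 gave 53 higher.

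Leaving out each sample in turn, which assumes that the lone sample varies like the other groups, gave 155 to 272 changed genes for E2 (98 to 148 higher, 57 to 124 lower). For EE it gave 188 to 285 (114 to 148 higher, 74 to 137 lower), and for EE against E2 21 to 111 (14 to 61 higher, 3 to 50 lower). Lists called ranged from 6 to 8 for each estrogen against placebo and from 2 to 5 for EE against E2. An estimated correlation called 0 lists in each comparison, and fry called 17, 22 and 1. The correlation of E2 and EE fold changes ranged from 0.906 to 0.934 with samples left out and was 0.898 without a filter. It was 0.884 and 0.869 with a different placebo sample for each estrogen, which leaves 1 control sample on each side. The reference gene ratio of highest to lowest sample was 1.21 by the median and 1.03 without its most variable gene.

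Some values turned sign. Scaled on reference genes, the reference gene median was -0.042 for E2 and -0.11 for EE. For E2, Ifng was then at -0.51, Il10 at -0.42, Irf7 at -0.25 and Prdm1 at -0.42. For EE, Ifng was at -0.74, Foxp3 at -0.57 and Prdm1 at -0.42. For EE against E2, Prdm1 was at -2.57e-04. On the median gene, Ifng was at -0.11, Il10 at -0.026 and Prdm1 at -0.021 for E2, and Ifng at -0.21 and Foxp3 at -0.046 for EE. With quantile normalisation, Ifng was at -0.21, Il10 at -0.41 and Prdm1 at -0.13 for E2, and Ifng at -0.45 and Foxp3 at -0.11 for EE. On column totals, Ifng was at -0.36, Il10 at -0.27, Irf7 at -0.11 and Prdm1 at -0.27 for E2, Ifng at -0.32, Foxp3 at -0.16 and Prdm1 at -0.0011 for EE, and Ifng at 0.041 for EE against E2.

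On positive controls the reference gene median was -0.10 for E2 and -0.36 for EE. Ifng was then at -0.57, Il10 at -0.48, Irf7 at -0.31 and Prdm1 at -0.48 for E2. For EE, Ifng was at -0.99, Tnfsf13b at -0.065, Foxp3 at -0.83, Prdm1 at -0.68 and Tubb5 at -0.013. For EE against E2, Prdm1 was at -0.20, Cd83 at -0.0045 and Gzma at -0.18. Ifng in EE was at -0.084 without a filter, at -0.014 with only these groups and at -0.30 after background subtraction. With samples left out, Ifng ranged from -0.015 to 0.22 and Il10 from -0.24 to 0.81 for E2, and Ifng from -0.19 to 0.17 for EE. For EE against E2, Ifng ranged from -0.27 to 0.063, Gzma from -0.18 to 0.64, Ctsg from -0.74 to 0.14 and Prdm1 from -0.00672 to 0.26. The sample numbers differ between all samples, so nothing paired them.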

Other observations

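The tests of genes and lists in this part were planned, while the ranges over scalings include those on column totals and positive controls and TMM without S100a8, S100a9 and Camp, which were chosen after the results were seen. Camera called the list of plasma cell and activated B cell genes in neither comparison with placebo (adjusted p = 0.664 for E2 and 0.48 for EE), and its median turned negative under some scalings, ranging from -0.46 to 0.22 for E2 and from -0.53 to 0.48 for EE, while fry called it (0.0488 and 0.0197). In E2 against placebo 4 of 9 tested members rose and 1 fell, led by Tnfrsf17, the receptor BCMA (1.38), and the secretory factor Xbp1 (0.72). In EE 6 rose and 1 fell, with Xbp1 at 1.13 and Cd27 at -0.84. Counts adjusted over the list alone were the same, but on reference genes 1 was higher and 6 lower in E2 and 2 were higher and 4 lower in EE. In E2 the call of Xbp1 was lost when scaled on reference genes (adjusted p = 0.475, range over the alternatives 3.08e-07 to 0.771), and in EE on positive controls (0.462, range 1.84e-16 to 0.462).

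The Th2 list went both ways, with 4 of 9 members higher and 2 lower in E2 (4 and 3 adjusted over the list alone) and 4 higher and 3 lower in EE; on reference genes 2 were higher and 4 lower in each, and its median also turned sign with the scaling, from -0.36 to 0.32 for E2 and from -0.53 to 0.48 for EE. The interleukin-33 receptor gene Il1rl1, which mast cells and other innate cells also carry, rose by 2.53 in E2 and by 3.02 in EE, and the eosinophil receptor gene Ccr3 rose by 1.25 and by 1.77. Among stromal and endothelial genes, Tgfb3 rose by 2.78 in E2 and by 2.97 in EE, Cd34 rose by 1.73 in E2, and Vcam1 rose by 1.35 in EE. Camera did not call the stromal list in E2 (adjusted p = 0.35), in EE (0.0947) or in EE against E2 (0.0514), while fry called it in each (0.00206, 3.90e-04 and 0.0132). Its median turned sign with the scaling in E2 (-0.34 to 0.34) and in EE against E2 (-0.10 to 0.36) and ranged from 0.055 to 1.06 in EE. On reference genes 2 members were higher and 3 lower in E2, 4 and 2 in EE, and 2 and 1 in EE against E2.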
